A study of Mus musculus with 18 samples.

How the data were processed

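The study measured messenger RNA of EDL, soleus and TA muscles from wild-type young and aged mice. Per the labels, total RNA was extracted with a kit for fibrous tissue (RNeasy Fibrous Tissue Mini) and libraries were made with the Clontech SMARTer kit for messenger RNA. The deposited file of each library lists transcripts with their length, effective length, TPM and read number. The deposited values used here were the expected counts per transcript, which are estimates and not whole numbers. The deposited TPM values were not tested themselves. The deposited length and effective length columns served for an offset in an alternative, with the TPM values as weights of the transcripts of a gene. The authors' notes name bcl2fastq, STAR 2.5.1a, Subread and featureCounts 1.4.6-p5, but those tools do not write this layout. The program that made the files, the genome build and the annotation are not given in the sources used here.

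Each file listed 86127 transcripts. Of these, 83739 (97.2%) had an identifier in GENCODE M21, the mouse annotation on GRCm38 used here for symbols, transcript-to-gene assignment and coordinates, and 87.6% of them had the same length there. The build is that of the reference and may not be the authors'. Transcripts that did not match held 0.221% to 0.325% of the reads. Expected counts were summed to 29542 genes and rounded. Genes of similar sequence share reads in ways the estimates cannot fully resolve, which touches Amy1, the fast myosins, H2 genes and Rps16.

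Groups came from the titles, which give muscle, age and replicate. For 4 libraries, all of EDL, the name inside the file name differed from the library name in the labels, and for 2 of these, EDL_Old 1 and EDL_Young 1, it carried the other age. These 2 were left out, a choice made before the data were examined, so that 16 libraries were used in 6 groups. The other 2 name the same age in both places. Genes of the Y chromosome had 0 reads in all 18 libraries, so no check of the animals by sex was possible.

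Genes with enough counts were kept with filterByExpr (minimum count 10), which left 10859. Scaling was by TMM. The test was edgeR's quasi-likelihood F test with robust dispersion, on 6 group means, two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of F. The comparisons were old against young in each muscle, the difference of these age changes between each pair of muscles, and the pairs of muscles in young mice. A fold change of a gene with 0 reads in a group was given as levels only.

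There were 26 lists of muscle processes and 13 of cell type markers, fixed before the data were examined, and 37 had at least 3 measured genes. They were tested with camera (preset correlation 0.01, log2 CPM with prior count 2) against all other genes, adjusted over lists and the comparisons of a kind. Camera with an estimated correlation was run beside it and is given beside each list. Some genes are on more than one list, such as the C1q genes of the complement and macrophage lists, and muscle itself expresses many of the markers.

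Genes were named by a rule fixed before the data were examined. It took the 6 highest and 6 lowest changes per age comparison among genes past the threshold with 5 CPM or more and no overlap of old and young libraries, up to 4 members per list by smallest p, genes called in all 3 muscles, and the largest differences between muscles. From these, the genes printed were picked after their values were seen, as were the few genes outside the rule, which were Prelp, Sbk2, Apod, Lgals3 and Tnfrsf23 in old soleus, Apod in old TA, and Ampd3, Dupd1 and Nrep in old EDL.

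Depth ran from 1154747 to 18305013 reads per library. Tested on simulated data of the same depths and spreads with known changes, the test recovered 68% of changes of 2 on the log2 scale in EDL, 80% in soleus and 71% in TA, and 20%, 42% and 28% of changes of 1. It called 5, 6 and 7 unchanged genes. With the libraries' GC trends added to the simulation, the EDL comparison called 60 unchanged genes, and 4 with the trend as an offset. In the same way soleus called 15 and 10, TA 0 and 6, and the difference of age changes between TA and EDL 22 and 3.

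Alternatives set before the data were examined were DESeq2 size factors, total counts, DESeq2, limma-voom, no filter, a filter of 1 CPM in 3 libraries, an offset for average transcript length, only the groups compared, a block for the replicate number, all 18 libraries by title or by file name, each replicate left out in turn, and fry for the lists. The filter of 1 CPM in 3 libraries was meant to be stricter but kept 11934 genes, more than the 10859 of the main fit. Chosen after seeing the data were an offset for lowess trends (span 0.3) of each library on GC content and length, log2 reads as a covariate, the trend offset with 18 libraries by either name, and the list tests with each library left out in turn. GC content and length had a value for all 10859 genes. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.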

Results

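RNA was sequenced from 3 hindlimb muscles of wild-type young and old mice. The soleus is a postural muscle rich in slow fibres, and the extensor digitorum longus (EDL) and tibialis anterior (TA) are made mostly of fast fibres. Each of the 6 combinations of muscle and age had 3 libraries, 18 in all. The numeric ages were not given in the sources used here, and neither was whether muscles came from shared animals. The main question was which genes differ between old and young muscle, asked in each muscle and then between muscles.

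The depth ranged from 1154747 to 18305013 reads per library. For replicates 1, 2 and 3 it was 2111006, 5337766 and 18305013 in old EDL, and 11857253, 3074106 and 2889317 in young EDL. Old soleus had 17092868, 5212732 and 5990326 reads, and young soleus 6570838, 5023210 and 2768398. Old TA had 1469222, 1866652 and 1154747 and young TA 4169196, 7658961 and 2216236, so each old TA library was shallower than each young one. Mitochondrially encoded genes took 11.25% to 29.14% of the reads. For EDL_Old 1 and EDL_Young 1 the title gives one age and the name of the attached file gives the other. Both were left out of the comparisons, so EDL had 2 old and 2 young libraries, against 3 and 3 in the other muscles. Levels below are read counts scaled to library size (CPM, TMM-normalised), as mean ± SD over the libraries compared, and changes are log2 fold changes of old against young unless stated.

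In old soleus, genes on the tendon list rose. These are markers of a tissue that a whole muscle sample can hold, and whether samples differed in its amount was not tested. Fmod, a collagen-binding proteoglycan (ENSMUSG00000041559, GRCm38 chromosome 1, 134037254 to 134048277), went from 15.1 ± 5.87 CPM in young to 115.7 ± 37.4 CPM in old (n = 3 each), a log2 change of 2.99 with SE 0.297 and adjusted p = 3.2e-05. Comp, a cartilage matrix protein (ENSMUSG00000031849, chromosome 8, 70373558 to 70382066), went from 4.38 ± 0.968 to 29.5 ± 2.03 CPM, a log2 change of 2.78 with SE 0.359 and adjusted p = 2e-04. Chad rose by 2.64, Angptl7 by 2.77 and Thbs4 by 1.14 on the log2 scale. The secreted matrix protein Prelp rose by 1.49, and the kinase-like gene Sbk2 by 1.51, from 52.6 ± 7.19 to 148.3 ± 31.7 CPM. Prelp and Sbk2 were chosen after their values were seen.

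Other genes higher in old soleus were the complement component C4b, by 1.80, and the complement inhibitor Serping1, by 0.84. The galectin gene Lgals3 rose by 2.02, the lipid-binding Apod by 1.34, the amylase gene Amy1 by 1.58, the decoy receptor gene Tnfrsf23 by 1.80 and the embryonic myosin Myh3 by 1.57. Slc22a2, with 0 reads in EDL and TA, rose by 2.23, and Cyp2f2 by 2.56. The 3 genes that fell were Adamts8, by 2.60, Nrep, by 1.31, and Lrtm1, by 1.12. Reads of Amy1 can be shared with similar gene copies, so its level is uncertain.

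Of 9 measured tendon genes in soleus, 4 rose (Fmod, Comp, Chad and Thbs4), none fell and 5 did not pass the test, with 4 adjusted over the list alone. The list test gave adjusted p = 3.33e-06, and adjusted p = 0.13 with an estimated correlation. Of 15 complement genes 2 rose and 13 did not pass, with 6 adjusted over the list alone, and all 15 log2 changes were positive (adjusted p = 2.69e-09, and adjusted p = 0.0909 with an estimated correlation). Of 18 antigen presentation genes none passed over all genes and 9 rose adjusted over the list alone (adjusted p = 9.79e-08, and adjusted p = 0.162 with an estimated correlation). Of 21 interferon response genes none passed, with 2 adjusted over the list alone (adjusted p = 0.000362, and adjusted p = 0.13 with an estimated correlation); Irf7 stood at 2.18 ± 0.626 CPM in young and 8.01 ± 5.06 CPM in old. The list test was higher in old for autophagy and lysosome genes (1 of 25 adjusted over the list alone, adjusted p = 0.0156, and adjusted p = 0.326 with an estimated correlation). It was lower for nuclear oxidative phosphorylation genes (0 of 45, adjusted p = 0.0213) and mitochondrially encoded genes (0 of 13, adjusted p = 0.00312). Both had adjusted p = 0.698 with an estimated correlation.

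Cell type markers shifted in soleus with these gene groups. The list test was higher in old for markers of macrophages (adjusted p = 0.00111, and adjusted p = 0.162 with an estimated correlation), with 2 of 13 past the test adjusted over the list alone. It was higher for adipocytes (7 of 11 adjusted over the list alone, adjusted p = 0.000282, and adjusted p = 0.109 with an estimated correlation) and for fibro-adipogenic cells and fibroblasts (1 of 13 rose, Serpinf1, 3 adjusted over the list alone, adjusted p = 0.000261, and adjusted p = 0.109 with an estimated correlation). Smooth muscle and pericyte markers gave 5 of 12 adjusted over the list alone (adjusted p = 0.0029, and adjusted p = 0.26 with an estimated correlation). Of 12 developmental fibre genes 1 rose, Myh3, with 3 adjusted over the list alone (adjusted p = 0.000282, and adjusted p = 0.109 with an estimated correlation). Of 18 denervation genes none passed, with 1 adjusted over the list alone (adjusted p = 0.000758, and adjusted p = 0.151 with an estimated correlation). Soleus_Old 2 stood apart within these 2 lists, with Myog at 85.5 CPM against 8.17 and 8.04 in the other old soleus libraries and Runx1 at 19.8 against 1.56 and 2.30, genes chosen after their values were seen. Without that library the developmental list had adjusted p = 0.0027 and the denervation list 0.0111, with 1 and 0 genes adjusted over the list alone. With each library left out in turn 10 of the 13 lists past the list test in soleus stayed; nuclear oxidative phosphorylation, autophagy and mitochondrially encoded genes did not, the last at adjusted p = 0.926 without Soleus_Old 1, whose mitochondrial share was 11.25% against 19.61% and 19.16% in the other old libraries.

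The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 27 of 10859 genes in soleus, 24 higher and 3 lower in old. The count was 12 without Soleus_Young 2, 13 without Soleus_Young 1 and 13 without Soleus_Young 3, while 14 passed with an offset for average transcript length. With a per-library GC and length trend removed, 17 of the 27 stayed, and Angptl7, Chad, C4b, Serping1, Serpinf1, Cyp2f2, Nrep and Lrtm1 had adjusted p from 0.0503 to 0.0862; the median absolute log2 change of the 10 lost calls went from 1.23 (SE 0.234) to 1.03 (SE 0.227), while Angptl7 stayed at 2.74 (SE 0.478, from 0.437).

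In old TA, a p53-responsive receptor gene, a phosphatase gene and an acetylcholine receptor subunit rose, and a fast myosin and the slow-fibre list genes Myl3 and Myoz2 fell. Eda2r, a p53-responsive receptor of the tumour necrosis factor family (ENSMUSG00000034457, GRCm38 chromosome X, 97333840 to 97377216), went from 6.57 ± 1.18 to 37.3 ± 11.2 CPM (n = 3 each), a log2 change of 2.47 with SE 0.364 and adjusted p = 0.000779. Dupd1, a dual-specificity phosphatase gene (ENSMUSG00000063821, chromosome 14, 21676537 to 21714576), rose from 20.3 ± 0.697 to 87.7 ± 24.9 CPM, a log2 change of 2.12 with SE 0.245 and adjusted p = 4.75e-05. Chrna1, a subunit of the acetylcholine receptor, rose by 2.11 and Ampd3, an AMP deaminase, by 1.79. The fast IIa myosin Myh2 fell by 1.87 (ENSMUSG00000033196, chromosome 11, 67171027 to 67197517), from 1963 ± 755 to 537 ± 144 CPM.

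Cpne2 rose by 3.48, Tnfrsf23 by 2.18, Apod by 1.39, the small heat shock gene Hspb8 by 1.14, Amy1 by 1.09 and the ribosomal protein gene Rps16 by 1.09 in TA. The sarcomere gene Myoz2 fell by 1.52, the slow light chain Myl3 by 1.51, Pdlim1 by 1.32 and Smtnl1 by 1.21. Chrng, the fetal acetylcholine receptor subunit, stood at 0, 0.139 and 0 CPM in young and 7.89, 9.61 and 14.0 CPM in old TA, and did not pass (adjusted p = 0.0698). Runx1 stood at 0.140 ± 0.242 and 13.3 ± 7.74 CPM (adjusted p = 0.139), and the p53 target Cdkn1a at 10.97 ± 2.79 and 37.5 ± 15.0 CPM (adjusted p = 0.467). Reads of Myh2, Rps16 and Amy1 can be shared with similar copies.

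Of 18 denervation and neuromuscular junction genes in TA, 1 rose (Chrna1) and 17 did not pass, with 9 adjusted over the list alone. The list test gave adjusted p = 1.61e-05, and adjusted p = 0.109 with an estimated correlation. Of 13 slow-fibre genes 2 fell (Myl3 and Myoz2) and 11 did not pass, with 4 adjusted over the list alone (adjusted p = 0.00073, and adjusted p = 0.162 with an estimated correlation). Among those not called, Tnnc1, Tnnt1 and Atp2a2 had higher means in old and the others lower ones. Tnnc1, Tnnt1 and Atp2a2 stood at 9.51, 10.16 and 14.77 CPM in young and 10.13, 13.53 and 17.47 CPM in old. Of 44 ribosomal protein genes 1 rose, with 3 adjusted over the list alone (adjusted p = 3.47e-07, and adjusted p = 0.433 with an estimated correlation). Of 24 fatty acid oxidation genes none passed; 1 rose and 4 fell adjusted over the list alone (adjusted p = 0.00553, lower in old, and adjusted p = 0.379 with an estimated correlation). Of 12 developmental fibre genes none passed, with 2 adjusted over the list alone (adjusted p = 0.00376, and adjusted p = 0.13 with an estimated correlation). Lists higher in old with no gene past either adjustment were proteasome subunits (27 genes, adjusted p = 0.00596), mitochondrially encoded genes (13, adjusted p = 0.00755), antigen presentation (18, adjusted p = 0.0379) and atrophy genes (16, adjusted p = 0.0487), with adjusted p = 0.647, 0.725, 0.698 and 0.162 with an estimated correlation.

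Markers of connective tissue were lower in old TA by the list test. Of 9 tendon genes none passed over all genes and 5 fell adjusted over the list alone (adjusted p = 8.34e-06, and adjusted p = 0.13 with an estimated correlation); Fmod stood at 34.3 ± 4.59 CPM in young and 12.3 ± 2.39 CPM in old (adjusted p = 0.106), while Comp and Wif1 had few or no reads in old TA, at 0.334 and 0 CPM. Fibro-adipogenic and fibroblast markers gave 1 of 13 lower adjusted over the list alone (adjusted p = 0.00101, and adjusted p = 0.13 with an estimated correlation). Extracellular matrix genes gave 3 of 28 lower adjusted over the list alone (adjusted p = 0.0162, and adjusted p = 0.545 with an estimated correlation). Endothelial markers gave 0 of 14 (adjusted p = 0.0102, and adjusted p = 0.425 with an estimated correlation) and erythroid markers 0 of 6 (adjusted p = 0.00941, and adjusted p = 0.48 with an estimated correlation). B and plasma cell markers gave 3 of 4 higher adjusted over the list alone (adjusted p = 0.000261, and adjusted p = 0.141 with an estimated correlation), and Igkc stood at 86.0, 7.80 and 1.002 CPM in the 3 old TA libraries. With each library left out in turn 6 of the 15 lists past the list test in TA stayed. The slow-fibre list had adjusted p = 0.174 without TA_Old 1, and 8 lists were lost without 2 to 5 of the 6 libraries: extracellular matrix, endothelial, erythroid, fatty acid oxidation, proteasome, mitochondrially encoded, antigen presentation and atrophy.

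The same test called 24 genes in TA, 17 higher and 7 lower in old. The count was 9 without TA_Old 2, 15 without TA_Old 3, 13 without TA_Young 1, 11 without TA_Young 2 and 15 without TA_Young 3. With the GC and length trend removed it was 52, 21 of them among the 24, and Chrna1, Myl3 and Amy1 had adjusted p = 0.0678, 0.0568 and 0.23 at log2 changes of 2.04, -1.52 and 0.95, near those above, with SE up from 0.321, 0.219 and 0.221 to 0.415, 0.298 and 0.295.

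In old EDL, slow-fibre genes rose from a low level in the libraries compared. Whether the rise goes with age rests on the titles of the EDL libraries with conflicting ages. With these included, the 8 slow-fibre calls had a median log2 change of 2.62 by title, with 8 called. By file name the median was 0.715, with 0 called. Myh7, the slow myosin heavy chain (ENSMUSG00000053093, GRCm38 chromosome 14, 54970684 to 54994626), went from 2.33 ± 1.75 to 74.6 ± 4.82 CPM (n = 2 each), a log2 change of 4.96 with SE 0.654 and adjusted p = 0.00469. Tnni1, the slow troponin I (ENSMUSG00000026418, chromosome 1, 135779434 to 135810989), went from 9.82 ± 1.98 to 118.6 ± 18.4 CPM, a log2 change of 3.59 with SE 0.373 and adjusted p = 1.87e-05. Tnnt1 rose by 2.77, Tnnc1 by 2.66 and Myl3 by 2.52. In young soleus Myh7 stood at 3174 ± 303 CPM (n = 3), so old EDL remained far below it.

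Some genes called in old TA were also higher in old EDL, with Dupd1 up by 2.36, Eda2r by 2.17, Ampd3 by 1.70 and Hspb8 by 1.19. Of the 24 genes called in TA, 16 had the same sign of change in EDL. Of the 193 genes called in EDL, 95 (49.2%) had the same sign in TA. The acetylcholine receptor subunit Chrnd rose by 2.21, the ubiquitin ligase Trim63 by 1.21, Lgals3 by 2.96, the fructose kinase Khk by 3.16 and Amy1 by 1.48. The insulin receptor substrate Irs1 fell by 1.54, the cell cycle inhibitor Cdkn1b by 2.45, the Wnt antagonist Wif1 by 2.49, the collagen gene Col1a2 by 1.13, Rc3h1 by 1.71 and Nrep by 1.32. Cdkn1a stood at 10.3 ± 4.43 and 44.1 ± 8.06 CPM and did not pass (adjusted p = 0.155).

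Of 13 slow-fibre genes in EDL, 8 rose and 5 did not pass, with 8 adjusted over the list alone. The list test gave adjusted p = 5.2e-09, and adjusted p = 0.0909 with an estimated correlation. Of 18 denervation genes 1 rose, Chrnd, with 9 adjusted over the list alone (adjusted p = 0.000362, and adjusted p = 0.135 with an estimated correlation). Of 12 developmental fibre genes 1 rose, Actc1, with 5 adjusted over the list alone (adjusted p = 0.000361, and adjusted p = 0.109 with an estimated correlation). Of 18 antigen presentation genes H2-T22 and H2-T23 rose, with 10 adjusted over the list alone (adjusted p = 1.47e-05, and adjusted p = 0.266 with an estimated correlation), and reads of this family can be shared between members. Of 25 autophagy and lysosome genes 3 rose (Map1lc3a, Sqstm1 and Ctsz), with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.00144, and adjusted p = 0.162 with an estimated correlation). Of 19 chaperone genes 3 rose (Hspb7, Hspb8 and Cryab), with 6 higher and 2 lower adjusted over the list alone, and the list test did not pass (adjusted p = 0.433).

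Other lists moved with them in EDL. Of 9 tendon genes 1 fell, Wif1, with 5 adjusted over the list alone (adjusted p = 0.00265, and adjusted p = 0.318 with an estimated correlation). EDL_Young 2 stood apart in that list, with Fmod at 320 CPM and Chad at 64.1, against 156.6 and 24.2 in EDL_Young 3 and at most 145.8 and 26.7 in the old libraries compared; without EDL_Young 2 the tendon list had adjusted p = 0.0465 and no gene adjusted over the list alone. Of 6 erythroid markers none passed, with 1 higher adjusted over the list alone (adjusted p = 0.00553, and adjusted p = 0.438 with an estimated correlation). Of 13 mitochondrially encoded genes none passed, with 2 lower adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.508 with an estimated correlation). Of 20 glycolysis and glycogen genes none passed, with 2 higher adjusted over the list alone (adjusted p = 0.00553, and adjusted p = 0.698 with an estimated correlation), and of 27 proteasome genes 1 rose, Psmb5, with 2 adjusted over the list alone (adjusted p = 0.0237, and adjusted p = 0.701 with an estimated correlation). With each library left out in turn 6 of the 10 lists past the list test in EDL stayed. The tendon and erythroid lists had adjusted p = 0.057 and 0.0638 without EDL_Old 2, glycolysis 0.117 without EDL_Old 3 and proteasome 0.322 without EDL_Young 2. No list passed with an estimated correlation for old against young in any of the 3 muscles. The share of reads from mitochondrially encoded genes was 16.78% and 11.95% in old EDL and 21.25% and 20.87% in young EDL. It was lowest in the deep libraries Soleus_Old 1, EDL_Old 3 and EDL_Young 1 (11.25%, 11.95% and 15.2%). In the shallow old TA libraries it was 26.95% to 29.14%. Old EDL libraries compared were deeper than the young ones and old TA libraries shallower. Depth and age thus cannot be told apart for the mitochondrially encoded list in these muscles, and depth runs with age there for every other gene too. With log2 reads as a covariate, a setting chosen after the data were seen, 24 of the 193 genes called in EDL stayed. In TA 14 of the 24 genes called stayed.

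The same test called 193 genes in EDL, 105 higher and 88 lower in old. The count was 9 without EDL_Young 2, 36 without EDL_Young 3, 11 without EDL_Old 3 and 1717 without EDL_Old 2, and over all 18 libraries it was 8 with ages from the titles and 1663 with ages from the file names; the calls were 96 higher and 239 lower with limma-voom, and 9 and 0 without EDL_Young 2, 11 and 0 without EDL_Old 3 and 8 and 0 by title. With the GC and length trend removed 73 passed, 50 of them among the 193, and Khk, Wif1, Nrep, Actc1, C4b, H2-T23, Map1lc3a, Sqstm1, Ctsz, Cryab, Psmb5 and Phlda3 had adjusted p from 0.0657 to 0.438; the 143 lost calls went from a median absolute log2 change of 1.28 (SE 0.302) to 0.704 (SE 0.247), while Wif1 stayed at -2.40 (SE 0.636, from 0.655).

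**Figure D1:**
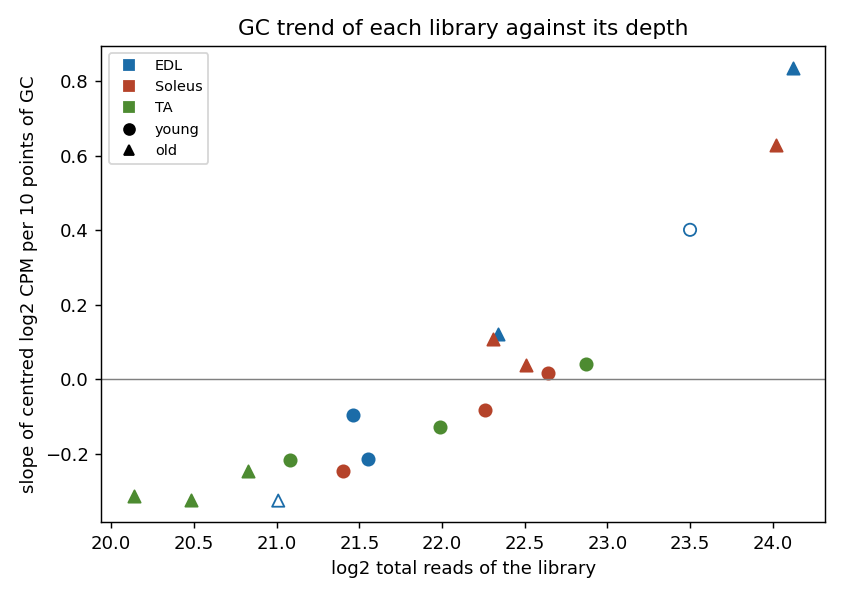
Slope of centred log2 CPM on GC content (log2 CPM per 10 points of GC) in each of the 18 libraries, against the log2 of its total reads; colours are muscles, circles young, triangles old, and hollow points the 2 EDL libraries with conflicting ages. Deeper libraries had higher slopes (Spearman's rho 0.938 over the 18 libraries), and the depths of old and young EDL differed in the libraries compared.

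**Figure D2:**
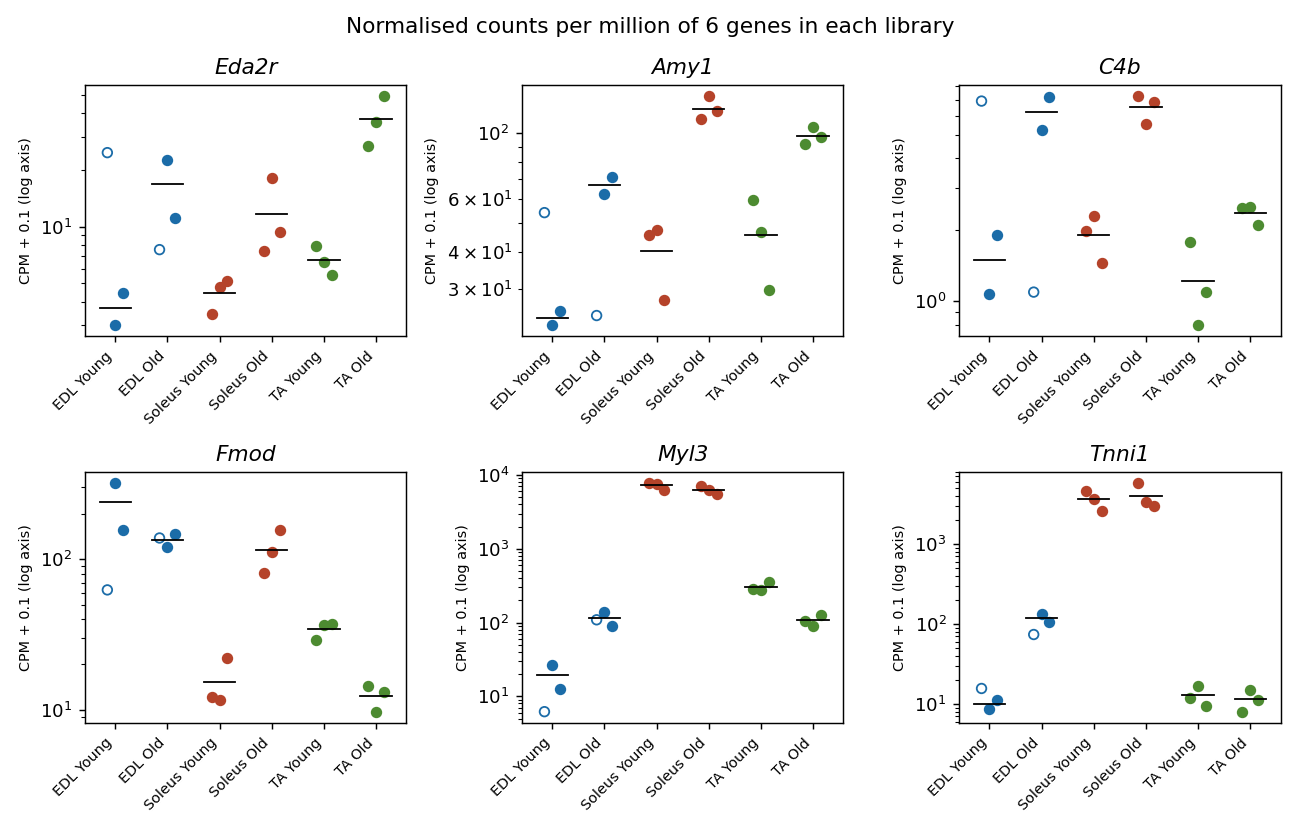
Normalised CPM (log axis, with 0.1 added) of 6 genes in each library, by muscle and age; filled points are the libraries compared, hollow points the 2 EDL libraries with conflicting ages, and lines the means of the filled points. Fmod was higher in old than in young soleus, at means of 115.7 and 15.1 CPM, and Tnni1 was higher in old than in young EDL, at 118.6 and 9.82 CPM.

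**Figure D3:**
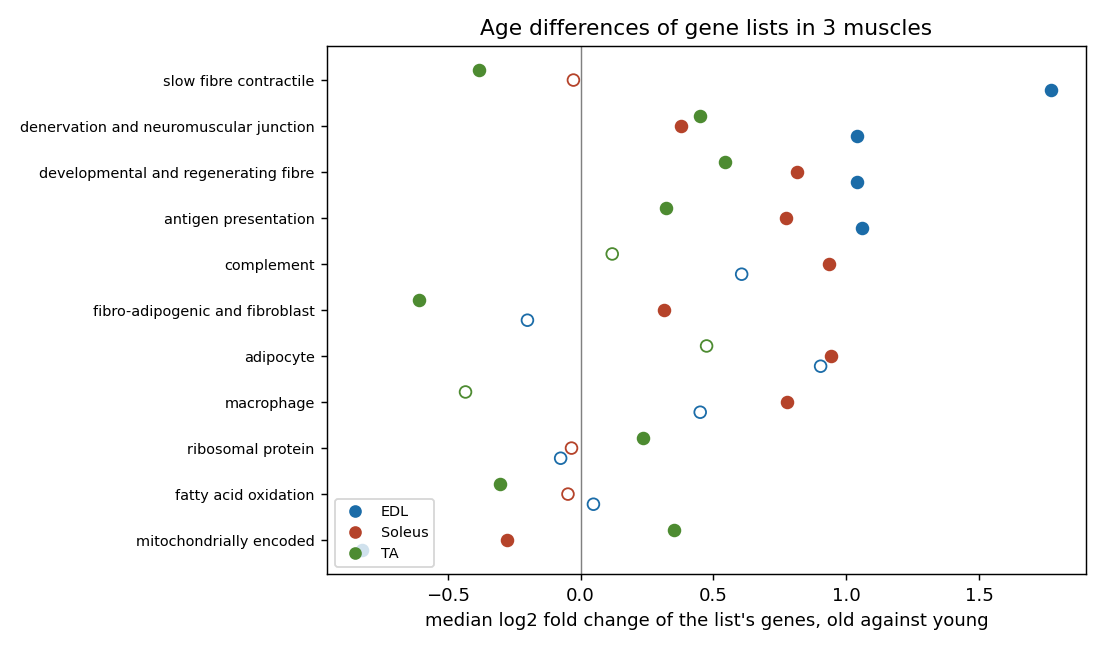
Median log2 fold change, old against young, of the measured genes of 11 lists fixed before the data were examined, with 1 point per muscle; filled points had an adjusted p under 0.05 in the list test with a preset correlation. None of them passed with an estimated correlation. The slow-fibre median was 1.77 in EDL and -0.384 in TA; the tendon list is not drawn, because its TA median rests on genes with few or no reads.

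Some age changes were shared between muscles. Amy1 was the 1 gene called in all 3 muscles, always higher in old. EDL and TA shared 8 higher genes, among them Eda2r, Dupd1, Ampd3 and Hspb8, where 0.164 were expected from independent lists (Fisher's exact test, adjusted p = 7.92e-12). By sign alone, 95 of the 193 EDL calls (49.2%) went the same way in TA and 177 (91.7%) in soleus. EDL and soleus shared 3, Amy1, C4b and Lgals3, against 0.232 expected (adjusted p = 0.00306 by Fisher's exact test). Soleus and TA shared 3, Amy1, Apod and Tnfrsf23, against 0.0376 expected (adjusted p = 1.9e-05 by Fisher's exact test). Nrep fell in EDL and soleus, and no lower gene was shared with TA. Age changes in EDL and soleus both rose with GC content (Spearman's rho 0.594 and 0.547 across genes). The number expected from independent lists may thus be too low for this pair. With the GC and length trend removed, C4b missed the edgeR threshold in EDL and soleus (adjusted p = 0.124 and 0.0627). Nrep missed it in both as well (0.119 and 0.0627), and Amy1 in TA (0.23). Amy1 and Lgals3 stayed in EDL and soleus, and Eda2r, Dupd1, Ampd3 and Hspb8 in EDL and TA.

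In all, 13 genes were called the same way in 2 muscles or more. The Fisher tests treat genes as independent, which they are not. The number of shared genes was 3 with all 18 libraries by title and 27 with DESeq2.

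The age change was called different between muscles for 14 to 29 genes per pair, by a test with little reach: in simulated data the test between TA and EDL recovered 43% of differences of 2 on the log2 scale and 3% of differences of 1. With the libraries' GC trends simulated as well it called 22 unchanged genes, and 3 with the trend as an offset. Between soleus and TA, 14 genes differed, 13 of them more positive in soleus. Fmod differed by 4.49 (SE 0.459, adjusted p = 5.15e-05), Prelp by 2.49, Thbs4 by 2.11 and Sbk2 by 2.10, and the phosphatase gene Dupd1 by -1.58. Of 9 tendon genes 3 differed, with 6 adjusted over the list alone (adjusted p = 3.32e-09, and adjusted p = 0.0787 with an estimated correlation). With the GC and length trend removed 10 of the 14 stayed, and Fmod had adjusted p = 0.05 at a difference of 4.23, with SE up from 0.459 to 0.694.

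Between soleus and EDL, 19 genes differed, 9 more positive in soleus and 10 more positive in EDL. The tendon and joint genes Fmod, Chad, Prg4 and Prelp differed by 3.83, 3.46, 2.58 and 1.94, and the slow-fibre genes Tnni1, Tnnc1, Tnnt1 and Myl3 by -3.45, -2.97, -2.80 and -2.73. Of 9 tendon genes 4 were more positive in soleus, with 6 adjusted over the list alone (adjusted p = 3.59e-13). Of 13 slow-fibre genes 7 were more negative in soleus, with 9 adjusted over the list alone (adjusted p = 7.07e-14). Both lists had adjusted p = 0.0369 with an estimated correlation. Removing the GC and length trend left 15 of the 19, and Chad and Myl3 had adjusted p = 0.0681 and 0.107 at differences of 3.79 and -2.47, with SE up from 0.575 and 0.349 to 0.694 and 0.476. Without EDL_Young 2, where Fmod, Chad and Prelp stood at 320, 64.1 and 65.7 CPM against 156.6, 24.2 and 32.9 in EDL_Young 3, Chad, Prg4 and Prelp had adjusted p = 0.143, 0.246 and 0.504 at differences of 2.59, 2.31 and 1.35, and Fmod passed at 3.22.

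Between TA and EDL, 29 genes differed, 4 more positive in TA and 25 more positive in EDL. Myl3 differed by -4.04 (SE 0.361, adjusted p = 2.2e-07), Tnni1 by -3.79, the small heat shock gene Hspb7 by -2.11 and the tropomyosin gene Tpm3 by -2.07. The 4 genes in the other direction were Rbm26, Rc3h1 and Upf2, by 2.03, 1.70 and 1.61, and AA474408, by 2.13. Of 13 slow-fibre genes 7 were more negative in TA, with 11 adjusted over the list alone (adjusted p = 1.92e-11, and adjusted p = 0.0369 with an estimated correlation). With DESeq2 size factors 24.2% of the calls were more positive in TA, against 13.8% with TMM. Removing the GC and length trend left 13 of the 29, and Rbm26, Rc3h1 and Upf2 had adjusted p = 0.114, 0.142 and 0.0786 at differences of 1.46, 1.02 and 1.12. Old libraries were the deeper ones in the EDL libraries compared and the shallower ones in TA, so this comparison also runs with depth. With log2 reads as a covariate, a setting chosen after the data were seen, 4 genes were called, 3 of them among the 29. In these 3 comparisons every other list past the list test with the preset correlation had adjusted p = 0.0564 or more with an estimated correlation. With each of 10 libraries left out, the tests with an estimated correlation missed the threshold in 6 for slow-fibre and 8 for tendon genes between soleus and EDL and in 5 for slow-fibre genes between TA and EDL, at adjusted p up to 0.163.

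The comparisons with EDL rest on its 2 libraries per age. The count between TA and EDL was 1272 without EDL_Old 2, 8 without EDL_Old 3, 5 without EDL_Young 2 and 16 without EDL_Young 3, and also 12 without TA_Old 1, 8 without TA_Old 3, 12 without TA_Young 2 and 16 without TA_Old 2. Between soleus and EDL it was 7 without EDL_Young 2, 9 without Soleus_Young 1, 11 without Soleus_Young 2 and 11 without Soleus_Old 3, and between soleus and TA it was 8 without each of Soleus_Young 2, TA_Old 2 and TA_Young 2.

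Young muscles differed in their fibre programmes, which gives the scale for the age changes. Myh7 stood at 3174 ± 303 CPM in young soleus (n = 3), 11.8 ± 3.40 in TA (n = 3) and 2.33 ± 1.75 in EDL (n = 2), so soleus was higher by log2 8.02 than TA and 10.37 than EDL. The fast IIb myosin Myh4 (ENSMUSG00000057003, GRCm38 chromosome 11, 67238029 to 67260446) stood at 287 ± 260 CPM in soleus, 13270 ± 2945 in TA and 17370 ± 3360 in EDL, log2 differences of -5.53 and -5.92. Myh2 was higher in soleus than EDL by 2.52 and in TA than EDL by 1.85, and Myh1 lower in soleus than TA (-2.60). Mstn, a brake on muscle growth, was lower in soleus than TA (-5.20), as was Mybph (-5.53).

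All 13 slow-fibre genes were higher in soleus than TA, and all 13 fast-fibre genes lower, with 13 and 13 adjusted over the list alone (adjusted p = 9.79e-32 and 5.69e-22, and adjusted p = 0.000677 and 0.0145 with an estimated correlation). Of 20 glycolysis genes 17 were lower in soleus than TA and 3 did not pass, with 17 adjusted over the list alone (adjusted p = 5.47e-24, and adjusted p = 0.0392 with an estimated correlation, up to 0.0633 with 1 library left out). Of 24 fatty acid oxidation genes 20 were higher in soleus than EDL, with 22 adjusted over the list alone, and 12 were higher in TA than EDL, with 17 adjusted over the list alone (adjusted p = 8.94e-20 and 9.08e-20, and adjusted p = 0.00551 for each with an estimated correlation).

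Young EDL held more connective tissue transcripts than young TA. Of 9 tendon genes 6 were lower in TA than EDL, with 8 adjusted over the list alone (adjusted p = 3.13e-14, and adjusted p = 0.0145 with an estimated correlation), and Wif1, Dkk3, Chad and Angptl7 were lower in TA (-5.62, -4.97, -3.45 and -2.86). Of 13 fibro-adipogenic and fibroblast markers 5 were lower in TA, with 10 adjusted over the list alone (adjusted p = 2.41e-13, and adjusted p = 0.00395 with an estimated correlation). Without EDL_Young 2, which held the most Chad and Angptl7 (64.1 and 152.1 CPM, against 24.2 and 56.8 in EDL_Young 3), their differences were -2.58 and -1.97 (adjusted p = 0.00847 and 0.0605). The light chain Myl3 was higher in TA than EDL by 3.96.

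The test called 1159 genes between young soleus and TA (578 higher, 581 lower in soleus), 1063 between soleus and EDL (542 higher, 521 lower) and 168 between TA and EDL (76 higher, 92 lower in TA). With total counts alone as scaling, which moved the median of all genes by 0.29, 0.168 and -0.119, the splits were 1442 and 334, 811 and 397, and 50 and 118. Soleus against TA had 754 calls without Soleus_Young 1 and 754 without Soleus_Young 2, soleus against EDL 580 without EDL_Young 2 and 623 without EDL_Young 3, and TA against EDL 39 without EDL_Young 2, 64 without EDL_Young 3 and 95 without TA_Young 1.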

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

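The tests of the conflicting EDL names, of GC content, of depth and of labels, and the later carry-over tests, were chosen after the results were seen; the first carry-over tests in EDL and TA and the counts over other splits were not.

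The age change differed between muscles, by the test of the difference itself, for 14 genes between soleus and TA, 19 between soleus and EDL and 29 between TA and EDL. Between soleus and TA the log2 differences were 4.49 for Fmod, 2.49 for Prelp, 2.11 for Thbs4, 2.10 for Sbk2 and -1.58 for Dupd1. Between soleus and EDL they were 3.83 for Fmod, 3.46 for Chad, 2.58 for Prg4, 1.94 for Prelp, -2.73 for Myl3, -2.80 for Tnnt1, -2.97 for Tnnc1 and -3.45 for Tnni1. Between TA and EDL they were 2.13 for AA474408, 2.03 for Rbm26, 1.70 for Rc3h1, 1.61 for Upf2, -2.07 for Tpm3, -2.11 for Hspb7, -3.79 for Tnni1 and -4.04 for Myl3.

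Among 100 splits of the soleus and TA libraries, 2, the real one included, gave as many genes as the 14 whose age change differed, and the highest other split gave 22. This share was under 0.05, the bound written beforehand. It cannot set the real grouping apart, because that other split gave more genes than the real one. The real split of TA also divides shallow from deep libraries, so the count cannot tell age from depth. For old against young soleus the real split gave 27 genes and the highest of the others 1, for TA 24 and 1, and for young soleus against young TA 1159 and 0. In each of these 3 cases 1 split was as large, the real one, and the 10 splits are too few for a share under 0.05.

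In EDL_Young 1, a library outside the comparisons, Cdkn1a stood at 61.51 CPM and Eda2r at 24.62 CPM, above the other young EDL libraries at 7.12 and 13.4 CPM for Cdkn1a and 2.91 and 4.34 CPM for Eda2r. Over the 38 genes called higher with age in soleus or TA, on a scale from 0 (other young EDL) to 1 (other old EDL), EDL_Old 1 lay at -0.192 and EDL_Young 1 at 0.795, as their file names would have it, but over the 13 slow-fibre genes they lay at 1.02 and 0.0503, as their titles would have it. On the 17 genes higher in old TA they lay at -0.0634 and 1.36, which leaves depth open, because within EDL that scale itself runs from shallow young to deeper old libraries. The slope of these 17 genes on log2 reads was higher over the EDL libraries than within the soleus and TA groups by 0.535 (95% interval 0.098 to 0.973), but that rested on 1 library, as without Soleus_Old 1 the interval was -0.0769 to 1.01. On the 24 genes higher in old soleus both lay among the young, at -0.492 and -0.528 (other young libraries -0.537 to 0.537); a wrong age and depth cannot be told apart as the source of these positions, since the gene sets point in opposite ways and depth runs with the scale, and a true difference between animals stays open and was not tested.

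Slow-fibre genes were higher in old EDL, with a median log2 change of 2.59 (median SE 0.327) for the 8 calls. With the GC and length trend removed 7 of the 8 stayed past the threshold at a median of 2.26 (SE 0.367), which argues against that trend as the whole cause; the bound for this was reset after a first one, a fall of less than the SE, had left it undecided. Ages from the file names gave a median of 0.715 with 0 of 8 called and ages from the titles 2.62 with 8 called. The rise was found without the 2 libraries with conflicting ages, so these fits cannot test a wrong age as its source. Whether the rise goes with age rests on the titles being right. Soleus tissue carried over stays open: 9 members of the list implied a share of 1.86% (1.6 to 2.68), and the 21 genes first chosen, outside the lists and far higher in young soleus than in young EDL, implied 6.9% (1.12 to 9.27) and so met what was written beforehand, but they were picked on the same young EDL libraries and sit near the floor, and 14 abundant genes chosen instead on soleus against TA, with limits set after results under more than one limit were seen, implied 3.92% with an interval of -1.15 to 7.93. In TA, where Myl3 and Myoz2 fell, the 15 outside genes implied a loss of -0.573% (-3.79 to 0.745), an interval too wide for the bound written beforehand, while Myl3 and Myoz2 implied losses of 2.88% and 7.92%, but the 7 other members that are abundant in soleus and far lower in EDL implied 0.0378% (-0.127 to 0.151) and left room for at most 0.957% of soleus tissue in young TA, which argues against its loss as the source of these 2 calls (over all 11 members not called the median was 0.151%, -0.0194 to 6.19, with Ankrd2 and Csrp3, well expressed in TA itself, at 17.3% and 35%); a change of fibre type with age may be at work in either muscle and was not tested.

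The EDL age changes tracked GC content. Spearman's rho across genes between log2 change and GC content, with genes not independent replicates, was 0.594 in EDL, 0.547 in soleus and -0.22 in TA, and each library's GC slope rose with its depth (rho 0.938 and Pearson's r 0.927 over 18 libraries, permutation p = 1e-05 for each, the smallest these permutations can give, and adjusted p = 2.5e-05 over 10 relations; r 0.936 without the 2 libraries farthest from the median depth). Within muscles rho was 0.943 in EDL, 0.771 in soleus (exact permutation p = 0.103) and 0.943 in TA, and r was 0.981, 0.963 and 0.983. Over all 193 EDL calls the median absolute log2 change went from 1.32 (SE 0.302) to 0.874 (SE 0.251) when the trend was removed, against 1.8 to 1.76 in soleus and 1.63 to 1.71 in TA, so a depth-linked GC trend is a candidate explanation for part of the EDL changes. That 50 calls stayed and 143 were lost follows from the correction itself and decides nothing further, and a part of the trend that goes with age itself stays open.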

How the results depend on the processing

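The GC and length trend, the covariate of reads, the trend with 18 libraries and the list tests with 1 library left out were chosen after seeing the data; the other settings were not. The named age calls past the threshold in every alternative were Fmod, Comp, Amy1, Prelp and Sbk2 in old soleus and Eda2r, Dupd1, Ampd3 and Myoz2 in old TA (17 alternatives each), and Sbk2 and Thbs4 for the difference between these muscles (22), where Dupd1 was lost in 13 and Fmod and Prelp in 1. The other named calls were lost in 1 to 10 alternatives in soleus and in TA, with adjusted p up to 0.381 and 0.395, and the named EDL calls in 2 (Dupd1 among them) to 13 (Wif1) of 19. The named differences of age changes that involve EDL were lost in 1 (Fmod) to 10 (Chad) of 24 against soleus and in 2 (Myl3) to 17 (Rc3h1) of 24 against TA, with Upf2 lost in 16, Rbm26 in 14 and AA474408 in 13. Between young muscles, Myh7, Mstn, Mybph and Myh1 for soleus against TA (17), Myh7 and Myh2 for soleus against EDL (20) and Wif1 and Dkk3 for TA against EDL (20) passed in every alternative; Myh4 was lost in 3 for each soleus comparison, and Angptl7, Myh2, Myl3 and Chad in 5, 3, 2 and 1 for TA against EDL. Ampd3 reversed in EDL by title, to -0.135 (adjusted p = 1), and with the GC trend by title, to -0.232 (adjusted p = 0.998). In simulated data most changes of 1 on the log2 scale were missed, with 20%, 42% and 28% recovered in EDL, soleus and TA. Among genes with a mean count of 50 or more the recovery was 29.7%, 57.1% and 54.5%.

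DESeq2's own test gave 527 genes in EDL, 42 in soleus, 81 in TA, age differences of 49 genes between soleus and TA and 346 between TA and EDL, and 27 shared; limma-voom gave 335 in EDL, 15 in TA, and 6 and 3 for these differences. No filter gave 766, 200 and 189 for EDL, soleus and TA, age differences of 228, 100 and 671 for soleus against TA, soleus against EDL and TA against EDL, 316 for young TA against EDL and 113 shared. The filter of 1 CPM in 3 libraries, which kept 11934 genes against 10859, gave an age difference of 56 genes for TA against EDL. Total counts gave 47 for TA against EDL and 1776 for young soleus against TA, the median of age differences moving by 0.106 (soleus against TA) and -0.0724 (TA against EDL). The length offset gave 47 in EDL, 14 in soleus, age differences of 12 and 47 for soleus and TA against EDL and 6 shared. Fits of only the groups compared gave 140 in TA, 1844, 1768 and 314 for the young muscles and 21 shared.

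With 18 libraries by title EDL gave 8, age differences from EDL 10 for soleus and 8 for TA, and 3 were shared; by file name these were 1663, 12 and 554, with 269 for young TA against EDL. With the GC and length trend EDL gave 73, TA 52 and young TA against EDL 321. With the covariate these gave 25, 71 and 296, TA against EDL 4 and young soleus against TA 1814. Of these calls, 24 in EDL, 14 in TA and 3 for TA against EDL were among those of the main fit. The trend by file name gave 550 in EDL, an age difference of 99 for TA against EDL, and 1827 and 447 for young soleus and young TA against EDL; by title these were 7, 9, 1662 and 344, with 8 for the age difference of soleus against EDL and 3 shared. The cause was not tested for any of these, except that DESeq2, voom and the filters change the test or the genes tested, and fits of only the groups compared change the spread and the genes tested, 9523 in EDL, 10225 in soleus and 7098 in TA.

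A replicate block by age gave 10 for soleus against EDL, 48 for TA against EDL and 107 for young TA against EDL; the blocked age counts were 176, 26 and 28. The numbers did not show paired animals, as 14 pairs of the same number and age had a median residual correlation of -0.00477 (-0.309 to 0.27). The 28 pairs of the same age and another number had a median of 0.00304 (-0.493 to 0.493). The highest value joined EDL_Old 3 and Soleus_Old 1, the 2 deepest libraries. Depth can thus mask pairing, and shared animals stay open. The numbers are those of the titles, and the file names give EDL_Old 2 and EDL_Old 3 other numbers. Pairs and blocks with old EDL may thus join the wrong animals. With 2 EDL libraries per age the residuals of one mirror those of the other, which limits what these medians can show.

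Leaving out 1 library gave 9 (EDL_Young 2) to 1717 (EDL_Old 2) in EDL, 12 (Soleus_Young 2) to 34 (Soleus_Old 1) in soleus and 9 (TA_Old 2) to 24 (TA_Old 1) in TA. The age differences ranged over 8 to 18 for soleus and TA, 7 to 28 for soleus and EDL and 5 to 1272 for TA and EDL, the young muscles over 754 to 968 for soleus and TA, 580 to 959 for soleus and EDL and 39 to 138 for TA and EDL, and the shared genes over 5 to 14. In EDL this left an age with 1 library, taken to vary like the other groups.

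For the lists, fry gave adjusted p = 0.000883 for slow-fibre genes in EDL, 0.0134 for complement and 0.0191 for tendon genes in soleus, and 0.0191 for denervation genes in TA. With the GC and length trend removed, slow-fibre genes in EDL, complement genes in soleus and denervation genes in TA each had adjusted p = 0.0339 with an estimated correlation.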

Other observations

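No test in this part was chosen after the results were seen, except the list tests with each library left out in turn. The lists described here were picked from those tested after their values were seen.

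Young EDL stood apart from young TA in more than tendon genes. Of 18 tricarboxylic acid cycle genes none passed over all genes and 11 were higher in TA adjusted over the list alone (adjusted p = 1.2e-08, and adjusted p = 0.0207 with an estimated correlation). Of 13 macrophage markers 2 were lower in TA than EDL, with 4 adjusted over the list alone (adjusted p = 7.95e-07, and adjusted p = 0.032 with an estimated correlation), and of 15 complement genes 2 were lower, with 9 adjusted over the list alone (adjusted p = 5.73e-07, and adjusted p = 0.0392 with an estimated correlation). Of 28 extracellular matrix genes 5 were lower in TA, with 10 adjusted over the list alone (adjusted p = 3.53e-11, and adjusted p = 0.0392 with an estimated correlation). Young EDL was represented by 2 libraries here. With each of the 5 libraries left out in turn, the tests with an estimated correlation did not all hold. They missed the threshold in 4 fits for extracellular matrix, 4 for complement, 3 for macrophage and 1 for tricarboxylic acid cycle genes.

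Calcium handling and excitation genes separated soleus from both fast muscles. Of 21 measured, 2 were higher and 7 lower in soleus than TA, with 2 and 14 adjusted over the list alone (adjusted p = 8.35e-05, and adjusted p = 0.0186 with an estimated correlation). Against EDL 2 were higher and 10 lower in soleus, with 2 and 11 adjusted over the list alone (adjusted p = 0.00023, and adjusted p = 0.0208 with an estimated correlation). The latter test missed the threshold in 1 of the 5 fits with a library left out. Of 19 chaperone genes 5 were higher in soleus than TA and 6 higher than EDL, with 8 and 6 adjusted over the list alone (adjusted p = 0.000393 and 0.000101, and adjusted p = 0.138 and 0.104 with an estimated correlation).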
